A study of Arabidopsis thaliana with 6 samples.

How the data were processed

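Total RNA of mature stems was sequenced in 6 libraries, 3 titled as γVPE mutant and 3 as wild type. The authors deposited 1 table of FPKM (fragments per kilobase, scaled to the library's total) with 34484 identifiers and 6 columns of values. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1. The genome build, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The columns named WT were matched to the wild type titles by name and number. The columns named WT_V were matched to the mutant titles as the remaining group, because the header does not spell the genotype, so the sets are called by their labels throughout.

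Gene names came from a reference table of assembly TAIR10.1, and 32548 identifiers matched a locus while 1936 did not. The latter were 1385 ENSRNA identifiers, 285 organelle identifiers and 266 others. In 7247 identifiers the value was 0 in all 6 libraries, so a gene at 0 is described as listed at 0, and no fold is given against it.

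Depth was recovered from the steps of the FPKM values. Multiplied by the exon length in the TAIR10.1 annotation, which need not be the one the authors used, the values of a column were whole multiples of 1 step, within 0.02 counts, for 99.19% of 16035 genes with a single transcript and 59.62% of 26720 genes above 0 with a length. The scaling total was 49281000, 51013000 and 47386000 in the WT_V libraries and 40308000, 46467000 and 41001000 in the WT libraries. A single count in a 1 kb gene was worth 0.0196 to 0.0248 FPKM. These counts were used to describe the spread among libraries and to simulate data, not for the test. Spearman correlations were 0.9844 to 0.9891 within a set and 0.941 to 0.9419 between the sets. They were computed over all 34484 identifiers, including the 7247 at 0 in all 6 libraries, and not over expressed genes alone. The spread of abundant genes beyond the base ratio was computed from the median count of the class with over 5000 counts. An average gene by gene, added after that value was seen, gave 1.04% in WT_V and 0.59% in WT.

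Genes with a mean of 1 FPKM or more over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend, as WT_V minus WT, and Benjamini-Hochberg adjustment at 0.05. A log2 difference on this scale understates the change of genes with low values. Ratios in the text are ratios of mean FPKM. For γVPE an exact two-sided permutation test was added. In simulated data with the recovered spread, 19144 genes and 200 changed genes, the procedure recovered 83 of 100 genes changed 1.5-fold and 97 of 100 changed 2-fold, and called 5 of 18944 unchanged genes. The simulation used 1 variance to mean ratio (3.438) for all genes, as many increases as decreases and no general shift between the sets. It therefore says little about false calls in the real data, where most genes were called.

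A total of 28 gene lists with 449 members was fixed before the data were examined, together with the tests and the alternatives. Of the members, 428 matched the reference by symbol and 21 were kept as typed. Lists with 3 or more tested members were tested with limma's camera at a preset correlation of 0.01 without an intensity trend, which is its default, and again with an estimated correlation and with fry. The plan did not state the camera trend. A version with the trend was computed after the data were seen and is given as an alternative, because it changes a call. Another 6 lists (embryo regulators, endosperm, seed coat, fruit, phosphate starvation, iron deficiency) were written after the data were first looked at and appear in the closing part alone.

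Named genes followed a rule fixed beforehand. It took the 4 vacuolar processing enzyme genes with CEP1, XCP1, XCP2, MC9, BFN1 and RNS3, the 12 greatest increases and 12 greatest decreases among called genes whose sets did not overlap, and up to 4 called members of each list with the greatest change. LHCB1.3, RCA, CEP3, MC4 and LHCB1.5 were named after their values were seen, as were AT4, SPX3, SQD2, MGD3, BHLH101 and ADPG1 in the closing part.

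The alternatives were a pseudocount of 0.1 or 5, no filter, a minimum mean of 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, a replicate block, each library left out in turn, and organelle genes removed. Added after the data were seen were the averaging of each set into 1 sample, nuclear loci alone, leaving out genes under 1 FPKM in WT, the camera trend, and the added lists without the filter. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.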

Results

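The series asked how the transcriptome of the mature Arabidopsis thaliana stem differs between plants mutated in γVPE and wild type plants. γVPE (GAMMA-VPE, AT4G32940) encodes a vacuolar processing enzyme, a cysteine protease that matures vacuolar proteins and has been linked to plant cell death. Stems were labelled 42 days after flowering, from plants grown at 20 °C with 16 h of light and 8 h of dark. There were 6 libraries, 3 in each of 2 sets, and the values were FPKM for 34484 gene identifiers. One set of columns was named WT, for wild type. The other was named WT_V and was taken as the mutant because its names were the ones left over, since the header does not spell out the genotype. The scaling total recovered from the FPKM steps was 40308000 to 51013000 per library. The titles number 3 replicates per genotype while the series design text says that there were none, and nothing says that the libraries came from separate plants. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Those of the gene lists at the preset correlation set the members against the remaining genes and measure the spread across genes. Neither can be taken to measure the spread between plants.

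The transcript of the mutated gene was not lower in the libraries taken as the mutant. GAMMA-VPE stood at 328.1, 328.1 and 325.4 FPKM in the libraries labelled WT_V, and at 163.1, 164.4 and 162.8 FPKM in those labelled WT. The WT_V mean was 200.19% of the WT mean, with a log2 difference of 0.997 ± 0.0165 (SE, n = 3 per set). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The labels do not describe the allele, so the level of the transcript does not settle which set is the mutant. All directions below are therefore between libraries labelled WT_V and libraries labelled WT.

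The other vacuolar processing enzyme genes were also higher in WT_V. BETA-VPE, the seed storage protein processing enzyme, measured 31.9 ± 1.07 FPKM in WT_V and 6.91 ± 0.596 in WT (SD, n = 3). DELTA-VPE, known from the seed coat, measured 58.1 ± 0.973 against 0.104 ± 0.0804 FPKM, and ALPHA-VPE 17.9 ± 0.854 against 0.173 ± 0.0329 FPKM. All 4 members were called higher by limma. The list as a whole passed camera at the preset correlation (adjusted p = 0.00633, and adjusted p = 0.0844 with an estimated correlation). The WT_V libraries also had all 8 seed markers and all 11 tested flower and pollen markers higher. A change of these genes within the stem therefore cannot be told apart from a different mix of organs.

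**Figure D1:**
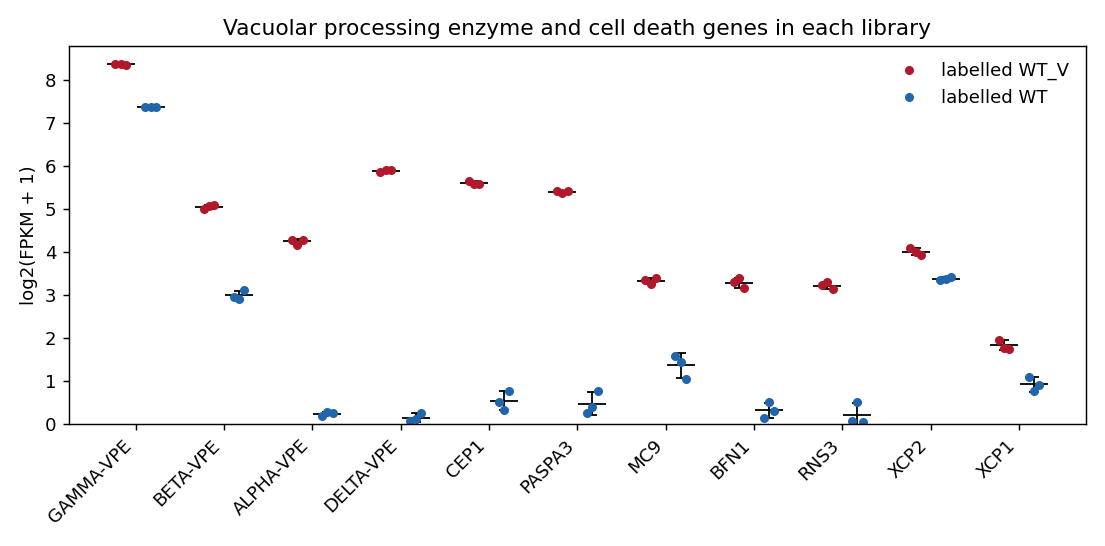
Expression of the vacuolar processing enzyme genes and of 7 cell death genes, as log2(FPKM + 1) on the vertical axis, in each of the 3 libraries labelled WT_V and the 3 labelled WT. Points are libraries, and the horizontal marks and bars are the mean and SD of each set. GAMMA-VPE lies near 327 FPKM in WT_V and 163 FPKM in WT, and every gene drawn is higher in WT_V.

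The sets differed most in seed genes. CRC (cruciferin C, a 12S globulin) stood at 3329, 3413 and 3408 FPKM in the WT_V libraries and was listed at 0 in each WT library. SESA3, a 2S albumin, stood at 3297, 3343 and 3296 FPKM, and CRA1 at 1656, 1677 and 1681 FPKM, and both were listed at 0 in each WT library. The 8 seed markers together made up 1.99 to 2.03% of all FPKM in WT_V, and all 8 were called higher by limma. As a list they passed camera (adjusted p = 5.66e-07, and adjusted p = 0.0656 with an estimated correlation). The 12 genes with the greatest increase included 9 named cruciferin, 2S albumin and oleosin genes. Flower and pollen markers moved the same way, with all 11 tested members higher in WT_V at a median log2 difference of 1.90 (adjusted p = 0.00102, and adjusted p = 0.0656 with an estimated correlation). That median was 1.215 with quantile normalization. AP3, a petal and stamen identity gene, measured 13.3 ± 0.104 FPKM against 1.60 ± 0.198, and SEP2 45.9 ± 1.76 against 6.22 ± 0.626.

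Of 19144 genes tested, 14550 passed an adjusted p of 0.05 in limma, 9931 higher and 4619 lower in WT_V. The median log2 difference of all tested genes was 0.167, 0.014 with median-of-ratios scaling and -0.09 with quantile normalization, so the direction of differences near that size depends on the scaling. With median-of-ratios scaling 7262 genes were higher and 6789 lower, and with quantile normalization 5711 were higher and 8596 lower. Changes of 2-fold or more were called for 2281 genes, 2077 higher and 204 lower in WT_V, and this split was 1782 to 389 with median-of-ratios scaling and 1168 to 760 with quantile normalization. Of the 2077 higher genes, 1125 averaged under 1 FPKM in WT. Leaving out all genes under 1 FPKM in WT, an alternative added after the data were seen, gave 1157 genes. By construction that filter removes genes raised from a low WT level and keeps genes that are lower in WT_V. The 3 values of one set lay apart from the 3 of the other for 77.55% of tested genes, where chance gives 10%.

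Cell death proteases and nucleases were higher in WT_V in most cases. Of 20 tested members of the xylem cell death and vacuolar hydrolase list, 18 were higher, 1 (CEP3) was lower and 1 (MC4) did not pass, at a median log2 difference of 1.402 (adjusted p = 0.00224, and adjusted p = 0.0656 with an estimated correlation). The median was 0.905 with quantile normalization, 0.909 without a filter and 0.607 with a minimum of 5 FPKM. Without genes under 1 FPKM in WT, 11 members were left, their median was 0.468 with adjusted p = 0.0851, and that filter by its construction takes out the most raised members, CEP1, PASPA3, RNS1, RNS3 and BFN1 among them. In the same libraries all 8 seed markers and all 11 tested flower and pollen markers were higher. Whether the cell death genes changed in stem xylem or came with other organs cannot be told from these values. CEP1, a cysteine endopeptidase of dying tapetum and other cells, measured 47.3 ± 1.38 FPKM in WT_V and 0.455 ± 0.226 in WT. The nuclease gene BFN1 measured 8.68 ± 0.784 against 0.244 ± 0.155 FPKM. PASPA3, an aspartic protease of developmental cell death, measured 41.1 ± 0.591 against 0.397 ± 0.272 FPKM, and RNS3 8.27 ± 0.519 against 0.163 ± 0.225. The metacaspase gene MC9 measured 9.00 ± 0.511 against 1.58 ± 0.481 FPKM. The xylem cysteine protease genes differed less, with XCP2 at 15.0 ± 0.935 against 9.33 ± 0.286 FPKM. XCP1 measured 2.54 ± 0.290 against 0.888 ± 0.221 FPKM, and its call ended with quantile normalization (adjusted p = 0.178).

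Secondary wall genes were higher in WT_V across several lists. All 9 members of the secondary wall cellulose list were higher (median log2 difference 0.99, adjusted p = 0.00299, and adjusted p = 0.0656 with an estimated correlation). The cellulose synthase gene CESA8 measured 14.9 ± 0.792 FPKM against 3.29 ± 0.148, CESA7 20.6 ± 0.334 against 8.61 ± 0.206, and CESA4 23.7 ± 0.808 against 10.8 ± 0.507. All 18 tested xylan synthesis genes were higher (median 0.74, adjusted p = 0.000773, and adjusted p = 0.0656 with an estimated correlation), among them GUX2 at 7.65 times its WT level. In the lignin monomer list 17 of 19 genes were higher and none lower (median 0.71, adjusted p = 0.00102, and adjusted p = 0.0656 with an estimated correlation), with PAL4 at 8.83 times and PAL1 at 3.08 times the WT level. In the lignin polymerisation list 12 of 13 were higher and 1 lower (median 1.21, or 0.812 with quantile normalization, adjusted p = 0.00299, and adjusted p = 0.0656 with an estimated correlation). The laccase gene LAC4 measured 45.2 ± 1.71 against 9.23 ± 0.187 FPKM. Of 23 tested secondary wall transcription factors 19 were higher and 3 lower, and the list did not pass (median 0.661, or 0.205 with quantile normalization, adjusted p = 0.0533). Among primary wall cellulose genes 8 of 9 were higher (median 0.44, or 0.272 with median-of-ratios scaling, adjusted p = 0.0193, and adjusted p = 0.147 with an estimated correlation). The same libraries had all 8 seed markers and all 11 tested flower and pollen markers higher. Those 8 seed markers were at about 2% of FPKM in WT_V, which does not measure the share of seed or flower RNA. The wall gene differences therefore cannot be assigned to stem xylem rather than to a different mix of organs.

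Flavonoid synthesis genes were higher in WT_V for all 11 tested members, at a median log2 difference of 3.48 (adjusted p = 8.15e-05, and adjusted p = 0.0656 with an estimated correlation). CHS, which encodes chalcone synthase, measured 169 ± 3.22 FPKM against 4.86 ± 0.902. DFR, which encodes dihydroflavonol reductase, measured 101 ± 3.29 against 1.62 ± 0.0901, and LDOX 82.4 ± 2.26 against 0.971 ± 0.438. These genes act in the seed coat as well as in vegetative tissue, and all 8 seed markers and all 11 tested flower and pollen markers were higher in the same libraries. The organ behind the flavonoid difference cannot be told from these values.

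Photosynthesis genes were lower in WT_V. Of 23 tested members 22 were lower and 1 higher, at a median log2 difference of -0.74 (adjusted p = 1.24e-13, and adjusted p = 0.0559 with an estimated correlation). The median was -0.911 with median-of-ratios scaling and -0.496 with quantile normalization. All 8 seed markers and all 11 tested flower and pollen markers were higher in the same libraries. Lower photosynthesis transcripts within the stem and a different mix of organs cannot be told apart here. LHCB1.3, a light harvesting protein gene, measured 3149 ± 71.2 FPKM in WT_V and 6001 ± 9.75 in WT. RCA, which encodes rubisco activase, measured 1859 ± 9.27 against 3104 ± 21.0 FPKM. The member that was higher was LHCB4.3, at 95.5 ± 2.95 against 15.7 ± 1.29 FPKM. The LHCB1 genes are near-identical copies, and LHCB1.5 was listed at 0 in all 6 libraries, so the values of the single copies are uncertain. The aliphatic glucosinolate list was the other list called lower than the remaining genes, with 6 of 11 members lower and 3 higher (median -0.11, adjusted p = 0.04, and adjusted p = 0.135 with an estimated correlation). This call ended with quantile normalization (adjusted p = 0.277), with a minimum of 5 FPKM (adjusted p = 0.0941), without WT replicate 3 (adjusted p = 0.0508) and without genes under 1 FPKM in WT (adjusted p = 0.0674). Its median was -0.281 with median-of-ratios scaling and -0.055 with organelle genes removed.

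Markers of phloem and epidermis and cell cycle genes were higher in WT_V, in the same libraries in which all 8 seed markers and all 11 tested flower and pollen markers were higher. Seeds and flowers also contain phloem, epidermis and dividing cells, so these markers do not separate a change within the stem from a different mix of organs. All 10 tested phloem markers were higher (median 0.91, adjusted p = 0.00224, and adjusted p = 0.0656 with an estimated correlation), with the sucrose transporter gene SUC2 at 112 ± 0.676 against 41.1 ± 0.907 FPKM. All 15 epidermis and cuticle markers were higher (median 1.05, adjusted p = 0.000557, and adjusted p = 0.0656 with an estimated correlation), with the wax synthesis gene MAH1 at 14.8 ± 1.33 against 2.97 ± 0.206 FPKM. All 16 tested cell cycle genes were higher (median 0.95, or 0.342 with quantile normalization, adjusted p = 0.000706, and adjusted p = 0.0656 with an estimated correlation), with the cytokinesis gene KN at 15.8 ± 1.15 against 2.83 ± 0.0512 FPKM. Of 10 cambium markers 9 were higher, and the list did not pass (median 0.62, adjusted p = 0.0736). Its median was 0.18 with quantile normalization and 0.377 with a pseudocount of 5.

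**Figure D2:**
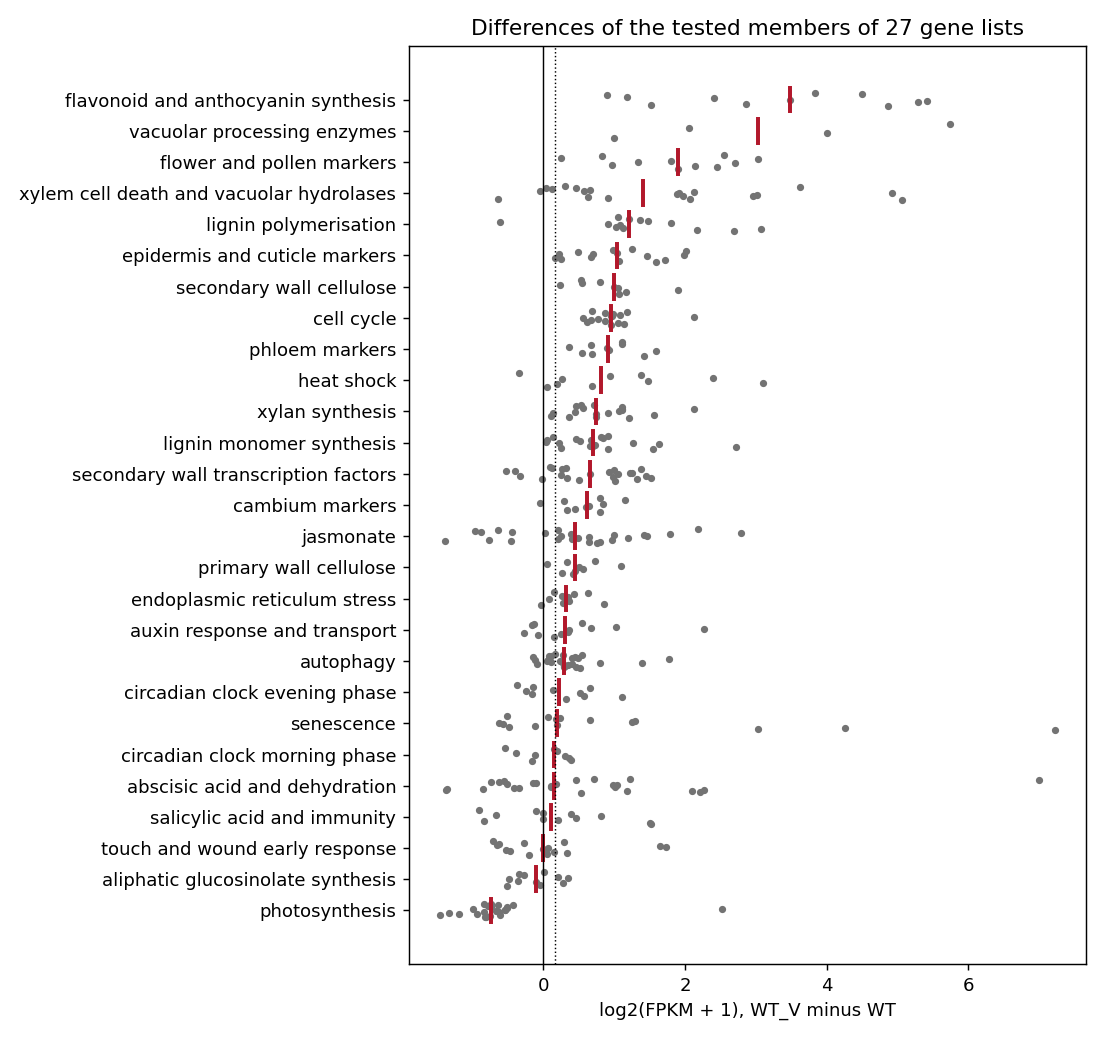
Log2(FPKM + 1) differences, WT_V minus WT, on the horizontal axis for the tested members of each gene list fixed before the data were examined, leaving out the seed markers. Grey points are genes, red bars are list medians, the solid line is 0 and the dotted line is the median of all tested genes, 0.167. Flavonoid synthesis has the highest median, 3.48, and photosynthesis the lowest, -0.74.

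Senescence genes went both ways. Of 15 tested members 8 were higher and 4 lower in WT_V, and the list did not pass (adjusted p = 0.763). Of all 19144 tested genes 9931 were higher and 4619 lower, a similar balance. SAG12, a senescence-associated cysteine protease gene, measured 163 ± 5.93 FPKM against 0.101 ± 0.0549, and the sucrose transporter gene SWEET15 77.8 ± 1.87 against 3.11 ± 0.282. Autophagy genes were higher for 22 of 28 members and lower for 2 (median 0.29, adjusted p = 0.0468, and adjusted p = 0.134 with an estimated correlation), with ATG8H at 3.59 times and ATG7 at 3.00 times the WT level. All 8 seed markers and all 11 tested flower and pollen markers were higher in the same libraries. Organ mix and a change within the stem cannot be told apart for these lists either. The autophagy median was 0.121 with quantile normalization and 0.128 with median-of-ratios scaling, where the call ended (adjusted p = 0.157). The call also ended with the replicate block (adjusted p = 0.0522), with nuclear loci alone (adjusted p = 0.0517) and without WT replicate 1 (adjusted p = 0.0642), replicate 2 (adjusted p = 0.0557) or replicate 3 (adjusted p = 0.0508).

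Hormone and stress lists did not pass. Their member counts stand against 9931 higher and 4619 lower among all 19144 tested genes. Jasmonate genes were higher for 18 of 26 members and lower for 7 (adjusted p = 0.322), with the storage protein gene VSP1 at 262 ± 2.54 against 36.8 ± 2.96 FPKM. Abscisic acid and dehydration genes were higher for 14 of 26 and lower for 11 (adjusted p = 0.762), and the seed-expressed gene LEA7 measured 161 ± 1.57 against 0.270 ± 0.0660 FPKM. Heat shock genes were higher for 8 of 10 and lower for 1 (adjusted p = 0.107). Endoplasmic reticulum stress genes were higher for 9 of 11 (adjusted p = 0.0544). Salicylic acid and immunity genes were higher for 6 of 12 and lower for 3 (adjusted p = 0.763), and auxin genes higher for 5 of 12 and lower for 3 (adjusted p = 0.835). Touch and wound genes were higher for 5 of 15 and lower for 7 (adjusted p = 0.0736). Morning clock genes were higher for 4 of 9 and lower for 2 (adjusted p = 0.578), and evening clock genes higher for 6 of 10 and lower for 4 (adjusted p = 0.961). The medians of the salicylic acid, abscisic acid, auxin, morning clock and touch lists changed sign under at least 1 scaling. Camera set the abscisic acid, salicylic acid and morning clock lists below the remaining genes although their medians were above 0. The touch list had a median of -0.011 and a mean of 0.052.

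In all, 16 of 28 lists passed with a preset correlation, 14 higher and 2 lower than the remaining genes, and 0 passed with an estimated correlation. The version with an estimated correlation uses the 4 residual degrees of freedom of these libraries. The preset version has degrees of freedom set by the number of genes. The estimate was below the preset 0.01 for some called lists, such as xylan synthesis (-0.0217) and cell cycle (-0.0486). For others it was above, such as seed markers (0.211). A lost call is therefore not by itself a sign of correlated members. The secondary wall transcription factor, endoplasmic reticulum stress, cambium, heat shock, jasmonate, evening clock and touch lists did not pass but did so under at least 1 alternative. By fry, which tests each list by itself, morning clock was the list that did not pass for a change in one direction (adjusted p = 0.496). The number of members called was the same when adjusted over the list alone, except for endoplasmic reticulum stress, where it was 10.

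Of the 204 genes called 2-fold or more lower in WT_V, 42 did not carry a nuclear locus identifier. Among the 12 with the greatest decrease, 8 carried ENSRNA or organelle identifiers. The phosphate starvation RNA IPS1 measured 55.5 ± 2.11 FPKM in WT_V and 206 ± 8.58 in WT. AT1G11175 measured 42.0 ± 1.04 against 144 ± 6.53 FPKM. Strand was not given in the sources used here, so genes that overlap or lie antisense to others are uncertain.

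**Figure D3:**
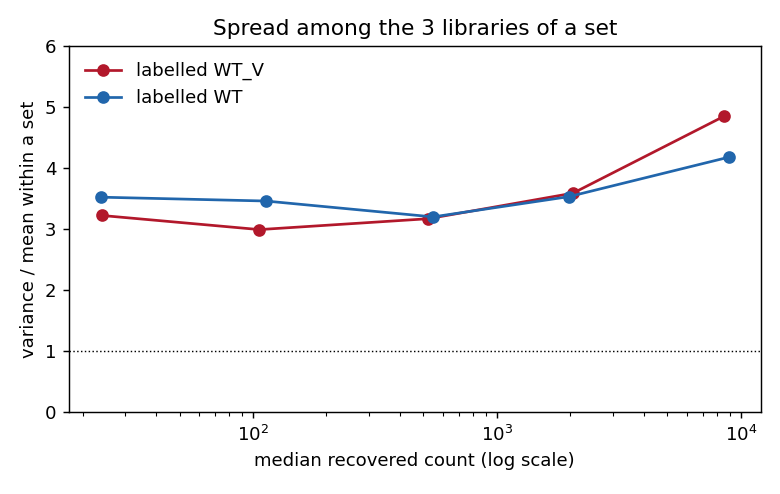
Variance over mean of the recovered counts among the 3 libraries of each set, on the vertical axis, against the median recovered count of 5 abundance classes on a log horizontal axis. Points are abundance classes, and the dotted line at 1 is counting noise alone. The ratio lies between 2.99 and 3.59 below a count of 5000 and reaches 4.85 in WT_V and 4.18 in WT above it.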

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

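The number of genes called kept within 1.5 times of 14550 under all alternatives run, from 11202 with a minimum of 5 FPKM to 16975 without a filter. Without each library in turn it was 13545 to 14292, the number with a change of 2-fold or more 2152 to 2406, the number of lists 14 to 17 and the γVPE log2 difference 0.994 to 1.001. The 2-fold count fell from 2281 to 959 with a pseudocount of 5, which shrinks the change of low genes by construction, and to 1130 with a minimum of 5 FPKM, which tests fewer genes. With a pseudocount of 0.1 it rose to 3011, 2699 higher and 312 lower. Among alternatives chosen after seeing the data, it was 1157 without genes under 1 FPKM in WT, 2219 for nuclear loci alone and 2286 by size alone from the averaged sets. The lists called fell from 16 to 0 with an estimated correlation, and rose to 21 without a filter and 19 with quantile normalization. With a pseudocount of 5 the medians of the vacuolar processing enzyme, xylem cell death, lignin polymerisation, flavonoid, cell cycle and flower lists shrank by over 1.5 times, to 1.888, 0.647, 0.799, 2.102, 0.47 and 1.042, and those lists still passed. With the camera intensity trend, also chosen after seeing the data, 17 lists passed, and 1 (photosynthesis) with an estimated correlation. The γVPE difference was 0.826 to 1.153 across the alternatives. Among the named genes, LHY reversed with quantile normalization (-0.519 against 0.39), and XCP1 and CESA9 no longer passed there, and the cause was not tested. The replicate numbers did not pair the libraries, since same-numbered deviations correlated between -0.016 and 0.014. A replicate block gave 14477 genes, 2283 with a change of 2-fold or more, 15 lists and 0.997 for γVPE. Depth limits the low genes, where 1 count in a 1 kb gene was worth 0.0196 to 0.0248 FPKM.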

Other observations

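The tests on loss of the transcript, exchanged labels, added seeds, spread within a set, other splits and the added lists without the filter were chosen after the result was seen, and those on the embryo, endosperm, seed coat, phosphate and iron lists were set before their values were computed. The lists of this part other than the stem lists were themselves chosen after the data were first looked at.

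Phosphate starvation genes were lower in the libraries labelled WT_V for 14 of 16 members and higher for 1, at a median log2 difference of -1.05. AT4, a non-coding RNA of phosphate starvation, measured 976 ± 11.2 FPKM in WT_V and 2723 ± 40.8 in WT (SD, n = 3). The sulfolipid synthesis gene SQD2 measured 116 ± 2.26 against 255 ± 1.80 FPKM, and the galactolipid synthesis gene MGD3 24.8 ± 0.0335 against 65.1 ± 0.770. IPS1, SPX3 and AT4 had been seen first. The other 13 members had a median of -0.964, and 11 of them were lower, which fits the hypothesis that the response as a whole differed between the sets. The median of these 13 stayed between -0.911 and -1.13 under the scalings tried. Whether phosphate supply, plant age, a different mix of organs or genotype lies behind it was not tested. Seed markers (all 8) and tested flower and pollen markers (all 11) were higher in the same WT_V libraries.

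Iron deficiency genes gave no such picture, with 2 of 7 tested members higher and 2 lower. Their median of -0.068 lies between the bounds set for the hypothesis, so it decides nothing. BHLH101 measured 0.752 ± 0.362 FPKM in WT_V and 4.11 ± 0.182 in WT. Of 8 fruit genes 5 were tested, and all 5 were higher in WT_V. Genes low in WT enter the test only through high WT_V values, and 3 of the 8 averaged 1 FPKM or more in WT. Without the filter the median log2 difference of all 8 was 1.02, against 1.103 for the tested members. ADPG1, a polygalacturonase gene of pod opening, measured 25.0 ± 0.961 FPKM in WT_V and 0.238 ± 0.0481 in WT.

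Seed storage genes reached 3383 FPKM (CRC) in WT_V and were at or near 0 in WT, and the WT libraries expressed 1 of 7 embryo, 0 of 8 endosperm and 3 of 9 seed coat genes at 1 FPKM or more. If seed tissue or seed RNA was in the WT_V libraries, each of these lists should have a median log2 difference above 1, and over the tested members the medians were 3.099, 2.086 and 1.904, but a gene at 0 in WT is tested only where its difference is at least 1.585. Without the filter they were 3.099 for embryo regulators, 1.726 for the seed coat and 0.733 for endosperm. The endosperm value lies between the bounds set, so the test as set decides nothing. Just 3 of the 8 endosperm genes reached the filter, and low values shrink a difference on this scale. That list is therefore a weak test of seed material. The embryo and seed coat lists go with seed material. Seeds added to an otherwise equal stem sample would lower the secondary wall cellulose, xylan, phloem and cambium medians unless seeds carry many such transcripts. That was not measured. The lowest median, cambium, was 0.623 ± 0.136 (SE of the median across its 10 genes, not across libraries). It was 0.48 ± 0.137 with median-of-ratios scaling and 0.18 ± 0.145 with quantile normalization. Each lies above 0 by more than its SE, the bound set against added seeds. The unmeasured seed level keeps the test from deciding. Added seeds, a different mix of organs, a different age of the material and genotype all stay open.

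γVPE was higher in the libraries labelled WT_V. Loss of the transcript there is argued against by a level of 200.19% of WT. An exchange of the labels would leave the WT libraries as the mutant, and their level of 49.952% of WT_V lies between the bounds set, so this cannot be told apart from correct labels while the allele is not described. A mutant that keeps a transcript stays open, and no test of it was possible with these values.

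Libraries of a set differed little, but by more than counting noise. The variance of the recovered counts was 3.128 times the mean in WT_V and 3.394 times in WT below a count of 1000, where counting noise alone gives 1, and what adds to counting noise was not tested. Beyond that ratio, the extra coefficient of variation of the most abundant genes was 1.419% in WT_V and 0.936% in WT, under the bound set for repeat measurements of 1 RNA pool per set, if the ratio itself is measurement noise. Pools of many plants could give a similar value and were not tested. If each set is 1 pool, the number of genes called describes these pools and not the genotypes.

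The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, 14550 genes were called and 2281 with a change of 2-fold or more, and the highest count of the other splits was 0 for both by limma, with 34 to 46 genes at an unadjusted p under 0.05. For gene lists the real split gave 16 and the highest other split 7. Each other split mixes the sets, so the difference between the sets enters both its contrast and its residual spread, and these counts are no reference for what chance gives.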
